A study of Lactiplantibacillus plantarum WCFS1 with 8 samples.

How the data were processed

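RNA from cultures of Lactiplantibacillus plantarum WCFS1 was measured on 8 one-colour microarrays, 2 for each of 4 carbon sources. Per the labels, the strain was passaged 5 times in MRS broth with 1% w/v of glucose, galactose, mannose or locust bean gum galacto-manno-oligosaccharides (GMOS), then grown in 30 ml duplicate cultures for 10 h to an optical density near 0.5. The titles of the GMOS arrays name the sugar as beta-manno-oligosaccharides, while the growth protocol names it as galacto-manno-oligosaccharides, and both were read as the same preparation. Per the labels, 500 ng of total RNA was reverse transcribed from an oligo-dT primer and labelled with Cy3 by in vitro transcription. The labels do not say whether the bacterial RNA was given a poly(A) tail first, so how transcripts were primed, and thus what share of each the signal reflects, is not known.

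The deposited scanner files hold spot intensity on a linear scale, 1 array per file. Per the file headers, the authors' processed intensity was background-subtracted and detrended with Agilent Feature Extraction 11.5.1.1, with no scaling between arrays. The authors also deposited a table of log2 values per gene, whose steps they did not state. Its 75th percentiles lay between 0.00 and 0.04, and its values correlated with those used here at 0.995 to 0.998 across the 3119 genes kept here on each array, so the table was read as log2 signal minus the 75th percentile of each array.

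The array design holds 9335 gene probes for 3122 genes, 3 probes for 3102 of them, in 15208 gene spots. The processed intensity was taken to log2 and each array's 75th percentile over gene spots was subtracted. The 4 spots marked as outliers over all arrays were left out, spots of a probe were averaged, and then the probes of a gene. A gene was kept when at least 1 probe was well above background on both arrays of at least 1 group, which held for 3119 genes. The share of gene spots well above background ran from 96.6% to 99.9% per array, and 0 spots were saturated. For arrays, the number of arrays limits the precision: the median standard error of a log2 fold change was 0.41 (2 arrays per group). Gene symbols, products and coordinates are those of the array design, which does not state a genome build. Symbols were given for 1359 genes, and other genes are named by locus tag. The design marked 228 probes of 76 genes as cross-hybridising.

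The fit was a group-means model in limma 3.58.1 (R 4.3.3, package data.table at 1.17.8) over all 8 arrays, with 4 residual degrees of freedom and a moderated spread. Tests were two-sided, adjusted by Benjamini-Hochberg over the 3119 genes within each of 5 comparisons, and a gene was called at an adjusted p under 0.05. Errors after ± are standard errors from this fit. The 5 comparisons were GMOS against glucose, mannose and galactose, and galactose and mannose each against glucose. Genes called higher, or lower, in GMOS than in each monosaccharide were counted. The overlap of responses was set beside 100 simulations with unchanged groups that kept the shared arrays and gave all groups the same spread. A panel of 26 gene lists, matched on symbols or products, was tested with camera at a preset correlation of 0.01, adjusted over 130 tests, with camera at an estimated correlation and fry beside it. No list called by camera at the preset correlation was called with an estimated correlation, where the lowest adjusted p was 0.449. The estimated form rests on the 4 residual degrees of freedom, so few lists could pass it over 130 tests. The list of capsular genes in GMOS against galactose had an estimated correlation of -0.0123, under the preset 0.01. Its unadjusted camera p still went from 6.20e-06 to 0.00621. A call lost with the estimated form thus does not show that correlation among genes explains it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

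Genes were named by a rule. In each comparison it took the called genes with the 12 largest rises and the 12 largest falls among those with non-overlapping groups and a known symbol or product, and up to 4 called members of each list. For the genes changed against each monosaccharide it took the 12 with the largest smallest change per direction. The members of the mannose phosphotransferase and carbon catabolite control lists and a fixed set of galactose and mannose genes were always taken, called or not. Not all of their values are given below. The groups, comparisons, lists, this rule and most alternatives were set before the data were examined. Genes outside the rule are said to have been chosen after their values were seen.

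The alternatives set in advance were a normexp background correction with offset 50 of the raw intensity, quantile normalization, median centring, no filter on dim probes and a stricter filter, the median of probes, the brightest probe, outlier spots kept, the authors' log2 table, a fit of the compared groups alone, the replicate number as a block, a trended and robust prior, a 2-fold minimum, and leaving out each array in turn. When an array was left out, the lone array of its group was assumed to vary like the other groups. The scan as a block, the first scan alone, the second scan alone, a fit without the galactose arrays and median centring for the lists were added after seeing the data, as was the amino acid list kept to synthesis genes. Per the file headers, glucose replicate 2 and GMOS replicate 2 were scanned after the other 6 arrays. All arrays lay on 1 slide, glucose and galactose in its first row and mannose and GMOS in its second, so comparisons that cross rows also cross sugars.

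The procedure was tested on simulated data in which 200 of 3119 genes were changed, in 5 draws per comparison. It recovered 11.3% to 17.0% of genes changed by 1 log2 unit, 86.9% to 90.1% of those changed by 2 and 99.7% to 100% of those changed by 4, and 3.37% to 7.39% of calls were false. The simulated genes were independent and had the same spread in every group. In the data, 34 genes differed over 2-fold between the glucose duplicates and 675 between the galactose duplicates. These rates thus need not hold for the data.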

Results

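Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium, was grown on 1 of 4 carbon sources, and the abundance of RNA was measured for 3119 genes. Galacto-manno-oligosaccharides (GMOS) from locust bean gum are short chains of beta-linked mannose with galactose side units. Glucose is the usual sugar of the medium, and mannose and galactose are the sugars that GMOS is built from. Each group held 2 arrays from duplicate cultures. The 75th percentile of spot intensity was 812 and 836 in the glucose arrays, 291 and 565 in galactose, 812 and 558 in mannose, and 520 and 541 in GMOS. Across genes, which are not independent replicates, the duplicates correlated at 0.989 in glucose, 0.913 in galactose, 0.965 in mannose and 0.959 in GMOS. Galactose replicate 2 correlated with the GMOS arrays at 0.957 and 0.954, higher than with its own duplicate. Between duplicates, 34 genes differed over 2-fold in glucose, 675 in galactose, 492 in mannose and 448 in GMOS.

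**Figure D1:**
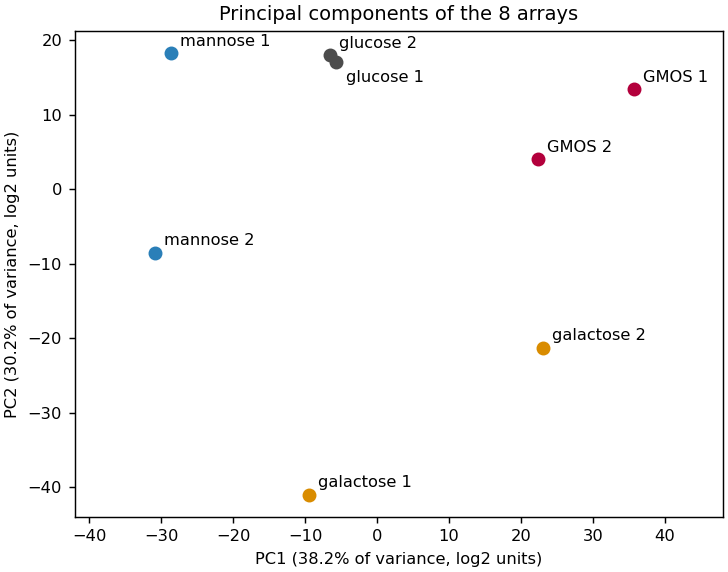
The 8 arrays on the first and second principal components of the log2 values, which held 38.2% and 30.2% of the variance (each point is 1 array, coloured by carbon source). The glucose arrays lie next to each other, while the galactose arrays lie apart on both axes, at -9.5 and 23.0 on the first.

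The comparison of GMOS with glucose asked which genes change when the oligosaccharide replaces the usual sugar. On GMOS, a cellobiose-type phosphotransferase system (PTS), a class of sugar importer that phosphorylates its substrate, and the neighbouring 6-phospho-beta-glucosidase gene were among the largest rises. The gene pbg6 (lp_3011, minus strand, 2678548 to 2679930) rose by 6.80 ± 0.59 on the log2 scale, or 112-fold (adjusted p = 0.000924), pts23B by 6.68 ± 0.49, pts23C by 6.61 ± 0.73 and pts23A by 4.06 ± 0.57. A cluster for sucrose and raffinose use also rose: the fructokinase gene sacK1 (lp_0184, 164479 to 165345) by 4.50 ± 0.44, the transporter gene pts1BCA by 4.37 ± 0.55, the hydrolase gene lp_0189 by 3.35 ± 0.48, the repressor gene scrR by 2.81 ± 0.58 and the sucrose-6-phosphate hydrolase gene scrB by 2.64 ± 0.52. The deepest falls were in amino acid genes: asnA (lp_0957, 888834 to 889802), which makes asparagine, was at -6.44 ± 0.79 (87.1-fold lower, adjusted p = 0.00331), its neighbour asnS1, which charges the asparagine tRNA, at -5.81 ± 0.76, and the tyrosine gene tyrA at -4.97 ± 0.55. Genes of maltose use fell too, with mapA (maltose phosphorylase) at -3.91 ± 0.46 and its neighbours malT at -3.61 ± 0.38 and galM2 at -3.59 ± 0.43.

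Of the 23 measured cellobiose and beta-glucoside PTS genes, 3 rose, 1 fell (pts30BCA, -2.68) and 19 did not pass the test (3 and 4 adjusted over the list alone). Among 92 amino acid biosynthesis genes, 11 fell and 0 rose (22 and 1 adjusted over the list alone). The list was matched on symbols and also took in 13 tRNA synthetase, 11 transporter and 3 regulator genes and a lysozyme gene, and asnS1 was 1 of the 11 fallen. The fallen members included aroF (chorismate synthase) at -4.76, aroE at -4.55 and aroI (shikimate kinase) at -4.16, all in the aromatic cluster that holds tyrA. The list's median was -0.72, or -0.59 in the first scan and -0.60 in the second, and its camera test gave an adjusted p of 6.92e-08, against an adjusted p = 0.466 with an estimated correlation. With the 64 synthesis genes of the amino acid biosynthesis list alone, a choice made after the values were seen, the median was -0.98 and the camera adjusted p 2.67e-11 (adjusted p = 0.466 with an estimated correlation). Among 9 genes of maltose and other sugar ABC transport, 5 fell (7 adjusted over the list alone), including mdxF at -2.32, mdxG at -2.28 and malS at -2.01. Their median was -2.01, with -1.57 and -2.45 in the first and second scan, and camera gave an adjusted p of 7.54e-08 (adjusted p = 0.466 with an estimated correlation). The peptide importer genes oppD at -4.20 and oppF at -3.31 were the 2 fallen members of 26 in the peptide list (6 adjusted over the list alone). None of the 18 fatty acid genes passed the limma test over all genes, 12 had an unadjusted p under 0.05, and 12 were lower when adjusted over the list alone.

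In the galactose and lactose list, 1 of 20 genes passed, galM2, which lies beside mapA and fell (1 higher and 1 lower adjusted over the list alone). Of the 20, 14 were above 0 and 6 had an unadjusted limma p under 0.05. The list's median was 0.52, or 0.45 in the first scan and 0.44 in the second. Its camera test, upward, gave an adjusted p of 0.0395 (adjusted p = 0.741 with an estimated correlation). The Leloir genes, which carry galactose into glycolysis, did not pass: galT stood at 1.24 ± 0.44 (adjusted p = 0.237), galE2 at 1.14 ± 0.44 and galK at 0.89 ± 0.41. The alpha-galactosidase gene melA stood at 1.39 ± 0.42 (adjusted p = 0.143) and the transporter gene rafP at 1.66 ± 0.46 (adjusted p = 0.113). For the 6 mannose PTS genes, 0 passed the limma test and 0 had an unadjusted p under 0.05, with a median of -0.89. That median was -0.18 in the first scan and -1.38 in the second, and it was -1.61 and -0.06 without GMOS replicates 1 and 2. The isomerase gene pmi, for mannose-6-phosphate, stood at 0.67 ± 0.34 (adjusted p = 0.494).

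In all, 73 genes changed between GMOS and glucose, 14 higher and 59 lower, and 382 had an unadjusted p under 0.05. Both GMOS arrays lay beyond both glucose arrays for each of the 73, and for 49.6% of all genes against 33.3% by chance. All 73 had the same sign and were over 2-fold inside each scan, which calls from these same 2 pairs largely fix. The count was 39 with quantile normalization, 142 with these 4 arrays alone, 141 without the galactose arrays, 54 with the scan as a block and 6 in the first scan alone, those being pts23A, pts23B, pts23C, pbg6, sacK1 and pts1BCA. It was 23 and 28 without glucose replicates 1 and 2, 141 without either galactose array, 41 without either mannose array, and 43 and 26 without GMOS replicates 1 and 2, the last with 11 higher and 15 lower. The value of scrR went to 1.75 without GMOS replicate 1, and aroI and aroE to -2.43 and -2.82 with normexp. Of the 35 called genes named by the rule, 16 passed without each array in turn. The genes aroF and aroE lost their call without GMOS replicate 2, and scrB, scrR, mdxF, mdxG, malS, oppD and oppF lost theirs without either glucose array.

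**Figure D2:**
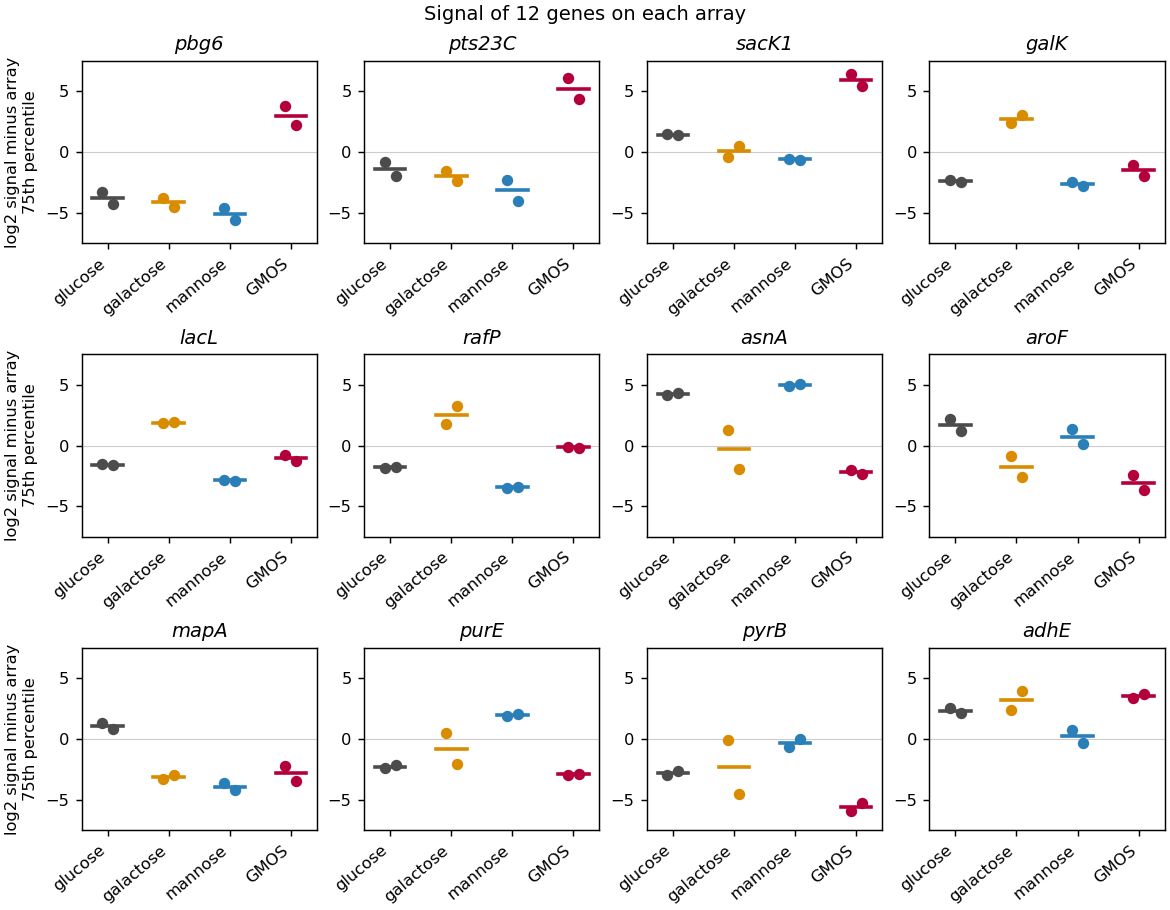
Log2 signal of 12 genes minus the 75th percentile of each array, by carbon source (points are single arrays, bars are the means of 2). The GMOS arrays stand above all others for pbg6, pts23C and sacK1, the galactose arrays for galK, lacL and rafP, and the mannose arrays for purE, while adhE is lowest on mannose.

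The comparison of GMOS with mannose asked how the oligosaccharide differs from the sugar of its main chain. The same PTS and sucrose clusters were higher on GMOS, with pts23C at 8.37 ± 0.73 (330.0-fold, adjusted p = 0.00033), pbg6 at 8.09 ± 0.59, pts1BCA at 6.82 ± 0.55 and sacK1 at 6.51 ± 0.44. Genes of glycerol use, of other sugar importers and of pyruvate conversion were higher too: glpD (glycerol-3-phosphate dehydrogenase) at 4.18 ± 1.00, glpF3 at 4.06 ± 0.94, the sorbitol importer gene pts38BC at 3.61 ± 0.60, the fructose importer gene fruA at 3.36 ± 0.56, adhE (alcohol dehydrogenase) at 3.32 ± 0.55 and pflA (formate lyase activation) at 3.24 ± 0.48. The neighbours asnA and asnS1 were lower on GMOS, at -7.15 ± 0.79 (adjusted p = 0.00164) and -6.62 ± 0.76, as were genes that make nucleotides: purE at -4.88 ± 0.67, purK1 at -4.69 ± 0.59, pyrC at -5.07 ± 1.18 and pyrB at -5.30 ± 1.08.

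By list, 12 of 18 purine genes fell and 0 rose (13 adjusted over the list alone), 9 of 16 pyrimidine genes fell (10 adjusted over the list alone), 5 of 18 fatty acid genes fell (12 adjusted over the list alone) and 30 of 92 amino acid genes fell with 1 rise (44 and 2 adjusted over the list alone). The 1 rise, named after its value was seen, was serS1, which charges the serine tRNA. The purine median was -3.10, at -2.82 with the scan as a block and -2.85 in the first scan, and its camera adjusted p was 6.00e-11 (adjusted p = 0.466 with an estimated correlation). Against glucose, 0 of the 18 purine genes were called on GMOS, with a median of -0.52, while the median on mannose was 2.47. Rises were found in 12 of 45 other PTS genes with 1 fall (15 and 2 adjusted over the list alone), 10 of 34 glycosidase genes (15 adjusted over the list alone), 8 of 36 glycerol and polyol genes (10 adjusted over the list alone) and 11 of 32 pyruvate genes with 1 fall (14 and 1 adjusted over the list alone). The pyruvate median was 0.83, at 0.97 with the scan as a block and 0.93 in the first scan, with a camera adjusted p of 7.33e-08 (adjusted p = 0.449 with an estimated correlation). On GMOS against glucose, 0 pyruvate genes and 0 glycerol and polyol genes were called, with medians of 0.35 and 0.12. Their medians on mannose against glucose were -0.26 and -0.29. In the galactose and lactose list, 4 of 20 genes rose (5 adjusted over the list alone): rafP by 3.28 ± 0.46, lacM by 2.13 ± 0.35, melA by 1.91 ± 0.42 and lacL by 1.82 ± 0.33. The lacL and lacM genes encode the subunits of a beta-galactosidase.

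Between GMOS and mannose 245 genes changed, 88 higher and 157 lower, with 649 at an unadjusted p under 0.05. Among all genes, 46.1% had non-overlapping arrays against 33.3% by chance. The scan as a block gave 83 higher and 104 lower, and the first scan alone 64 and 57. Quantile normalization gave 162, and normexp took pyrB to -2.87 and melA to 1.23. The count was 69 and 90 without mannose replicates 1 and 2, 23 without GMOS replicate 1, and 171 without GMOS replicate 2, with 91 higher and 80 lower. Of the 64 called genes named by the rule, 15 passed without each array in turn, among them asnA, asnS1, purK1, pts23C, pbg6, pts1BCA and sacK1 but no other gene given for this comparison.

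The comparison of GMOS with galactose set the oligosaccharide against the sugar of its side units. Galactose genes were much lower on GMOS: galK (lp_3482, 3090327 to 3091490) at -4.23 ± 0.41 (18.8-fold lower, adjusted p = 0.00105), galT at -4.20 ± 0.44, galE2 at -4.06 ± 0.44, lacL at -2.91 ± 0.33 and lacM at -2.85 ± 0.35. The 8 rises were the genes of the PTS and sucrose clusters alone, from pts23C at 7.20 ± 0.73 (adjusted p = 0.00116) and pbg6 at 7.14 ± 0.59 down to scrB at 3.54 ± 0.52. The PTS gene pts23A stood at 2.36 ± 0.57 and did not pass (adjusted p = 0.0609). Of the 20 galactose and lactose genes, 9 fell (10 adjusted over the list alone), with rafP at -2.67 ± 0.46 and melA at -2.68 ± 0.42. The list's median was -1.37, at -1.29 with the scan as a block and -1.26 in the first scan, and camera gave an adjusted p of 0.000101 (adjusted p = 0.485 with an estimated correlation). Of 37 capsular polysaccharide genes, which build the cell's sugar coat, 6 fell (26 adjusted over the list alone), among them cps2D at -2.70 ± 0.43, which went to -0.99 with normexp. The capsular polysaccharide median was -1.45, at -1.41 with the scan as a block, -1.40 in the first scan and -0.45 with quantile normalization. By cluster, the median was -2.01 in cps2, -1.52 in cps3 and -1.66 in cps4, but 0.72 in the 9 cps1 genes, where 0 passed the limma test and 0 had an unadjusted p under 0.05. These signs were the same with normexp, quantile normalization and median centring. Its camera adjusted p was 3.36e-05 (adjusted p = 0.449 with an estimated correlation), and 0.171 without galactose replicate 2. For 149 prophage genes, 0 passed the limma test, 81 had an unadjusted p under 0.05 and 64 were lower when adjusted over the list alone. The prophage median was -0.92, and -0.04 with quantile normalization, and the camera adjusted p of 1.02e-07 (adjusted p = 0.741 with an estimated correlation) was 0.180 with quantile normalization.

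In all, 35 genes changed between GMOS and galactose, 8 higher and 27 lower, and 792 had an unadjusted p under 0.05. Among all genes, 44.9% had non-overlapping arrays against 33.3% by chance. The median log2 fold change over all genes was -0.35, or -0.07 with median centring and 0.03 with quantile normalization. Rises and falls numbered 8 and 9 with normexp, 10 and 11 with quantile normalization, 8 and 7 with median centring, 8 and 5 with the scan as a block, 8 and 3 in the first scan alone, 11 and 62 with these 4 arrays alone and 13 and 257 with the trended and robust prior. The count was 20 without either glucose array, 18 and 549 without galactose replicates 1 and 2, 251 without either mannose array, and 13 and 14 without GMOS replicates 1 and 2. The genes pbg6, pts23B, pts23C, sacK1, pts1BCA, lp_0189, galK, galT and galE2 passed in every one of these fits. The genes scrB and scrR lost their call without galactose replicate 1, lacL and lacM lost theirs in the first scan alone, and rafP, melA, galR and the capsular genes named here lost their call in at least 1.

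Counted over these 3 comparisons, 8 genes were higher on GMOS than on each monosaccharide: pbg6, pts23C, pts23B, sacK1, pts1BCA, lp_0189, scrR and scrB. Independent lists of these sizes would share 0.00101 genes on average, and simulations with shared GMOS arrays gave 0. Neither is a chance level for this count. Independent lists leave out the shared arrays, and the simulations hold no changed genes, so few calls could arise in them. The genes sit in 2 clusters, the PTS cluster on the minus strand from 2675826 to 2679930 and the sucrose cluster from 164479 to 171853. The count was 8 with the scan as a block and 5 in the first scan alone, and from 6 to 10 with single arrays left out. The methionine gene metA was the 1 gene lower on GMOS than on each monosaccharide (-2.36, -2.69 and -2.32 against glucose, mannose and galactose). Its log2 signal on the GMOS arrays was low, at -6.52 and -6.46, so these changes rest on dim signal. It was not counted when only probes above background on all arrays were used. The count of 1 stood against 0.0257 by independent lists and 0 in the simulations, with the same limits. That count was 0 with normexp, quantile normalization, median centring and the scan as a block, 0 without either glucose array, without galactose replicate 1 and without either GMOS array. It was 80 without galactose replicate 2, and 4 and 6 without mannose replicates 1 and 2, where metA was not among them.

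**Figure D3:**
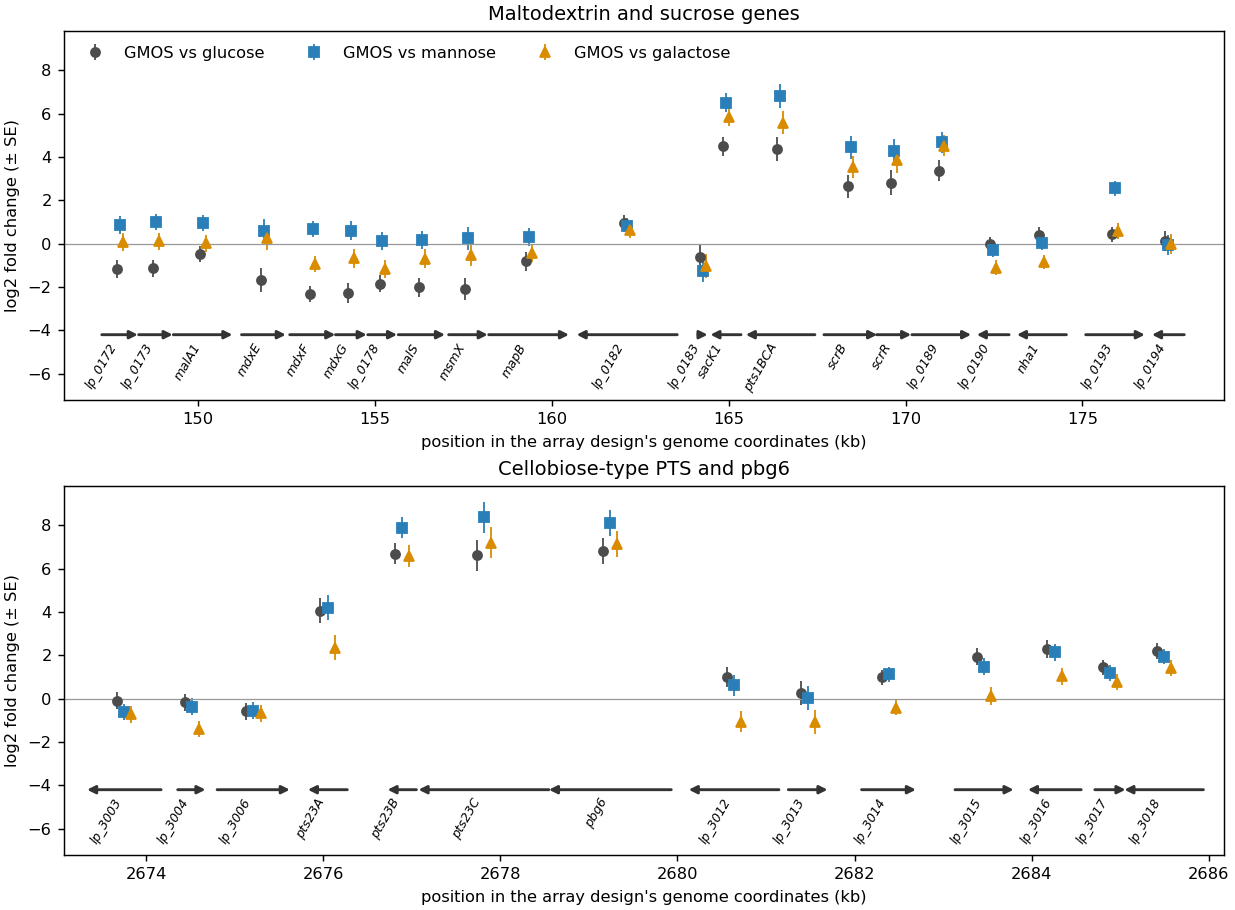
Log2 fold change of each gene (points, ± standard error, 2 arrays per group) by position in kilobases around the sucrose cluster and the cellobiose-type PTS cluster, with arrows for the genes and their strands. The rises from sacK1 to lp_0189 and from pts23A to pbg6 stand beside neighbours such as lp_0182 and lp_3012 that did not pass the test.

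The comparison of galactose with glucose asked which genes galactose alone changes. The Leloir genes rose most, galT by 5.45 ± 0.44 (43.6-fold, adjusted p = 0.000417), galE2 by 5.20 ± 0.44 and galK by 5.13 ± 0.41. Their neighbours followed, rafP by 4.32 ± 0.46, melA by 4.07 ± 0.42, lacM by 3.70 ± 0.35, lacL by 3.47 ± 0.33, the regulator gene galR by 3.48 ± 0.47 and galM3 by 3.02 ± 0.44. In the galactose and lactose list, 9 of 20 genes rose and 1 fell, galM2 (10 and 1 adjusted over the list alone). The list's median was 1.05, at 1.03 with the scan as a block and 1.14 in the first scan, and camera gave an adjusted p of 3.74e-05 (adjusted p = 0.485 with an estimated correlation). Of 37 capsular genes, 4 rose (13 adjusted over the list alone), all in the cps2 cluster: cps2C by 2.83 ± 0.50, cps2D by 2.75 ± 0.43, cps2F by 2.18 ± 0.35 and cps2E by 2.08 ± 0.32, with cps2C and cps2D at 1.56 and 1.54 under normexp. The maltose genes mapA (-4.19 ± 0.46), galM2 (-3.76 ± 0.43) and malT (-3.53 ± 0.38) fell, as did asnA (-4.56 ± 0.79) and tyrA (-3.39 ± 0.55). The galactose duplicates stood far apart for asnA, at 1.27 and -1.89, and its change was -2.98 without galactose replicate 2. Among the 6 mannose PTS genes, 0 passed the limma test, 2 had an unadjusted p under 0.05 and the median was -1.07. Their camera adjusted p was 0.00444 (adjusted p = 0.512 with an estimated correlation).

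In all, 28 genes changed between galactose and glucose, 16 higher and 12 lower, and 917 had an unadjusted p under 0.05; 57.6% of genes had non-overlapping arrays against 33.3% by chance. The median over all genes was 0.32, or 0.03 with quantile normalization and 0.16 with median centring, where 16 genes rose and 18 fell. The count was 46 with normexp, 13 with these 4 arrays alone, 332 with the trended and robust prior (298 higher and 34 lower), 11 with the scan as a block and 10 in the first scan alone, the last 10 being galT, galE2, galK, rafP, melA, lacM, lacL, mapA, malT and galM2. Those 10 passed in every alternative, while the count was 10 and 11 without glucose replicates 1 and 2, and 341 without either mannose array, 313 higher and 28 lower. Without galactose replicate 1 it was 55, 17 higher and 38 lower, and without galactose replicate 2 it was 50, 37 higher and 13 lower.

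The comparison of mannose with glucose asked which genes mannose alone changes. Purine synthesis genes rose, purK1 by 4.26 ± 0.59 (19.2-fold, adjusted p = 0.0125), purE by 4.23 ± 0.67, purQ by 3.90 ± 0.70 and purC by 3.79 ± 0.54, as did the purine transporter gene lp_0848 by 3.84 ± 0.72. In the purine list, 8 of 18 genes rose (12 adjusted over the list alone). Its median was 2.47, at 2.20 with the scan as a block and 2.17 in the first scan, with a camera adjusted p of 8.52e-18 (adjusted p = 0.449 with an estimated correlation). Genes for the use of other sugars fell: mapA was at -5.00 ± 0.46 (adjusted p = 0.00142), galM2 at -4.50 ± 0.43, malT at -4.45 ± 0.38, the cellobiose PTS gene pts7C at -4.81 ± 0.96, the beta-glucoside PTS gene pts33BCA at -4.19 ± 0.67 and the galactitol PTS gene pts35B at -3.70 ± 0.53, or -2.23 with normexp. Falls were found in 5 of 23 cellobiose and beta-glucoside PTS genes (9 adjusted over the list alone), 9 of 45 other PTS genes with 1 rise (20 and 1 adjusted over the list alone), 4 of 34 glycosidase genes (13 adjusted over the list alone), 5 of 9 maltose and sugar ABC transport genes (8 adjusted over the list alone) and 4 of 32 pyruvate genes (10 adjusted over the list alone). The other PTS median was -0.90, at -1.14 with the scan as a block and -1.06 in the first scan, with a camera adjusted p of 4.98e-15 (adjusted p = 0.449 with an estimated correlation). The pyruvate genes included pdhA at -2.89 ± 0.55 and pox1 at -2.49 ± 0.38. For the 6 mannose PTS genes, 0 passed the limma test, 2 had an unadjusted p under 0.05, and the median was -1.18, at -1.57 with the scan as a block and -1.24 in the first scan. The isomerase gene pmi stood at -0.59 ± 0.34 (adjusted p = 0.799).

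In all, 70 genes changed between mannose and glucose, 13 higher and 57 lower, and 288 had an unadjusted p under 0.05; 39.9% of genes had non-overlapping arrays against 33.3% by chance. The count was 32 with quantile normalization, 152 with these 4 arrays alone, 69 with the scan as a block and 5 in the first scan alone, all lower. It was 3, all lower, without either glucose array and without either mannose array, and mapA, malT and galM2 were the genes named by the rule that passed in every alternative, so the purine calls rest on all 4 arrays.

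The responses to GMOS and to each monosaccharide, all against glucose, were compared across genes, which are not independent replicates. The GMOS and galactose changes correlated at 0.557, against 0.501 in simulations of unchanged groups with shared glucose arrays, with a covariance of 0.405 against 0.103. Both sugars lowered 12 genes, against 0.227 for independent lists, which leave out the shared arrays, and 0.03 in the simulations, which leave out the effects, and they raised 0 in common. This overlap was counted in the main fit alone. With the scan as a block, 4 genes were lower on galactose than on glucose, so no more could be shared. The correlation was 0.714 without galactose replicate 1 and 0.290 without galactose replicate 2. The GMOS and mannose changes correlated at 0.097, against 0.500 in the simulations, with a covariance of 0.0609 against 0.103. The simulations held no effects and gave all groups the same spread. The shared glucose arrays differed by a median of 0.23, against 0.48 in GMOS, 0.51 in mannose and 0.55 in galactose. The simulated values are thus too high for what these glucose arrays share, and a value under them does not speak against a shared response. GMOS and mannose shared 12 lowered genes, against 1.08 for independent lists and 0.02 in the simulations, and 2 genes went opposite ways. This overlap too was counted in the main fit alone, and most mannose calls were lost when a glucose or mannose array was left out. Without GMOS replicates 1 and 2 the correlation of the GMOS and mannose changes was 0.291 and -0.123. The 6 genes lower on all 3 sugars than on glucose were mapA, malT and galM2 of maltose use, pgmB2, pts30BCA and the regulator gene lp_3521.

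Some lists had 0 called members in each of the 5 comparisons with limma: mannose PTS, mannose and amino sugar catabolism, carbon catabolite control, ribosomal proteins, chaperones, proteases and cold shock, ATP synthase, plantaricin and quorum sensing, and prophage. For galactose against glucose, however, 87 of 149 prophage genes had an unadjusted p under 0.05, and 59 were higher when adjusted over the list alone. The prophage median was 0.87, and 0.11 with quantile normalization, with a camera adjusted p of 1.88e-06 (adjusted p = 0.741 with an estimated correlation), or 0.161 with quantile normalization. Of 27 plantaricin and quorum sensing genes, 11 had an unadjusted p under 0.05 in each of the comparisons with galactose. Adjusted over the list alone, 5 were higher on galactose than on glucose and 6 were lower on GMOS than on galactose. The plantaricin and quorum sensing medians of 0.58 and -0.68 turned to -0.02 and 0.06 with quantile normalization. In the other lists without calls, at most 5 genes had an unadjusted p under 0.05 in a comparison (chaperones, GMOS against mannose). Adjusted over the list alone, 1 gene each of mannose and amino sugar catabolism and of carbon catabolite control was higher on GMOS than on mannose. Of the 5 measured carbon catabolite control genes, 1 at most had an unadjusted p under 0.05 in a comparison, and ccpA stood at 0.30 ± 0.38 on GMOS and -1.02 ± 0.38 on mannose against glucose. Against glucose, 55 of 56 ribosomal protein genes were above 0 on GMOS, with a median of 0.55 (0.50 and 0.57 in the first and second scan), 1 had an unadjusted p under 0.05, and camera gave an adjusted p of 1.71e-05 (adjusted p = 0.741 with an estimated correlation). The 13 glycolysis genes were all above 0 there, with a median of 0.59 (0.57 and 0.61 in the first and second scan, 0.35 without glucose replicate 2 and 0.38 without GMOS replicate 1), and camera gave an adjusted p of 0.00125 (adjusted p = 0.466 with an estimated correlation).

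**Figure D4:**
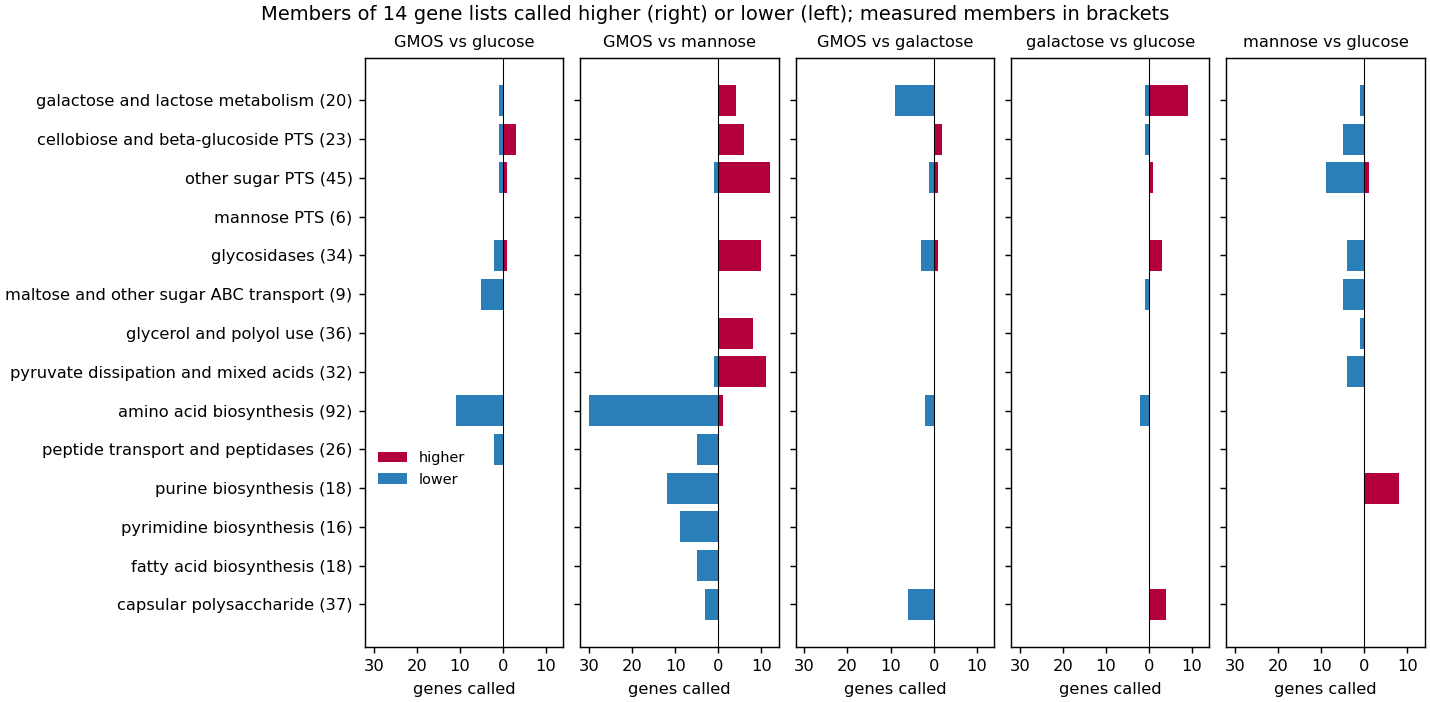
Number of measured members (in brackets) of 14 gene lists called higher (right) or lower (left) in each of the 5 comparisons, on a common axis of gene counts. Higher calls include 9 of 20 galactose and lactose genes on galactose and 8 of 18 purine genes on mannose, each against glucose, and lower calls include 11 and 30 of 92 amino acid genes on GMOS against glucose and mannose. Bars count single genes, and no list was called by camera with an estimated correlation (lowest adjusted p = 0.449). That form of the test rests on 4 residual degrees of freedom and could call few lists.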

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

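The scan as a block, the first scan alone, the second scan alone, the fit without galactose arrays, median centring of the lists and the amino acid list kept to synthesis genes were chosen only after the results were seen, while the others were fixed before any data were seen. Over 24 settings, 0 of the 188 called values of named genes reversed, and 106 kept their call in every fit fixed beforehand that left out no array. Causes were not tested, except that single scans, single arrays left out and fits of the compared groups alone have fewer arrays by construction.

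For GMOS against glucose the count of 73 went to 39 with quantile normalization, 142 in the fit of the compared groups alone, 6 in the first scan alone and 141 without the galactose arrays, and ran from 23 to 141 with single arrays left out. For GMOS against mannose, 245 went to 162 with quantile normalization and 121 in the first scan, and from 23 to 344 with single arrays left out. For GMOS against galactose, 35 went to 17 with normexp, 21 with quantile normalization and 15 with median centring. It was 73 in the fit of the compared groups alone, 270 with the trended and robust prior, 13 with the scan as a block and 11 in the first scan, and from 13 to 549 with single arrays left out. For galactose against glucose, 28 went to 46 with normexp, 13 in the fit of the compared groups alone, 332 with the trended and robust prior, 11 with the scan as a block and 10 in the first scan, and from 10 to 341 with single arrays left out. For mannose against glucose, 70 went to 32 with quantile normalization, 152 in the fit of the compared groups alone and 5 in the first scan, and from 3 to 86 with single arrays left out.

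The 8 genes higher on GMOS than on each monosaccharide became 5 in the first scan alone and 6 to 10 with single arrays left out. The 1 gene lower became 0 with normexp, quantile normalization, median centring, probes above background on all arrays, the brightest probe, the authors' table, the scan as a block and the first scan alone. It was 15 with the trended and robust prior, and 0 to 80 with single arrays left out. The correlation of the GMOS and galactose responses ran from 0.290 to 0.714 and that of GMOS and mannose from -0.123 to 0.291 with single arrays left out.

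The replicate block gave 96 genes for GMOS against glucose, 309 for GMOS against mannose, 75 for GMOS against galactose, 52 for galactose against glucose, 98 for mannose against glucose and 10 lower on GMOS than on each monosaccharide. The labels do not say that a number marks cultures grown together. Deviations of equally numbered arrays correlated at 0.304, 0.503 and 0.584 among glucose, mannose and GMOS and at 0.219 for glucose and galactose, but at -0.0865 and -0.0699 for galactose with mannose and GMOS. They were thus not alike in every pair, and the number was not taken as a pairing.

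Of 51 list calls by camera, 43 were kept with quantile normalization, 50 with median centring, 48 with the scan as a block, 48 in the first scan alone, 6 with fry and 0 with an estimated correlation. The directions of camera are relative to the other genes, and they turned for some lists. In GMOS against galactose, fatty acid biosynthesis genes were up without galactose replicate 1 (adjusted p = 0.0172), and their adjusted p ran from 0.00902 to 0.977 with single arrays left out. Glycerol and polyol genes were up there in the first scan (0.0372). In galactose against glucose, ribosomal proteins were up without galactose replicate 1 (0.00394, with 8.50e-13 to 0.126 over single arrays left out). Pyrimidine biosynthesis genes were up without galactose replicate 2 (0.752, the lowest being 9.01e-08). In mannose against glucose, amino acid biosynthesis genes were down without mannose replicate 1 (0.714, the lowest being 1.08e-10). Without mannose replicate 2, fatty acid genes were up (0.0242, the highest being 0.945) and prophage genes were down (0.0183, the highest being 0.958). The sign of fry differs from that of camera by construction for some lists, since fry tests against no change, and the values themselves did not turn. This held for metal and iron genes in GMOS against galactose (fry adjusted p = 0.0209, median -0.25, against -0.35 for all genes), and in galactose against glucose for ribosomal proteins (0.973) and amino acid genes (0.882), where fry gave no call.

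The median over all genes moved by over 0.1 with some scalings. For GMOS against glucose it was 0.03, and 0.25 with normexp and 0.16 with median centring. For GMOS against mannose it was -0.01, and 0.14 with normexp. For galactose against glucose it was 0.32, and 0.43 with normexp, 0.16 with median centring and 0.03 with quantile normalization. For GMOS against galactose it was -0.35, and -0.07 with median centring and 0.03 with quantile normalization. Per array 96.6% to 99.9% of gene spots were well above background, yet some GMOS falls (aroI, aroE) shrank with normexp.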

Other observations

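The test of low signal in a galactose array was set before its result was seen, while the tests of a mislabelled array, the slide row, the state of the cultures and cross-hybridisation were chosen only after the results they address were seen, as were the genes named in the next pair of paragraphs.

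All 5 genes of 1 branched-chain amino acid importer were called lower on GMOS than on glucose: livB at -3.59 ± 0.46, livD at -3.25 ± 0.45, livE at -3.09 ± 0.43, livA at -2.91 ± 0.36 and livC at -2.91 ± 0.46. Also lower were the ammonium transporter gene amtB at -2.21 ± 0.32 and the serine synthesis genes serA and serC at -2.57 ± 0.37 and -2.17 ± 0.36. Near the PTS cluster, lp_3016, lp_3018 and lp_3015 were higher on GMOS, at 2.29 ± 0.40, 2.19 ± 0.36 and 1.93 ± 0.40. The genes serA and serC belong to the amino acid list, while the others here belong to no list that was tested. None of these genes passed in the first scan alone.

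On mannose, the galactitol PTS genes pts35A and pts35C were at -3.19 ± 0.53 and -3.63 ± 0.54 against glucose, and xfp (phosphoketolase) nearby was at -2.48 ± 0.38. The genes iolG and iolE, annotated for inositol breakdown, were at -3.08 ± 0.53 and -2.79 ± 0.49, and the transporter gene iolT2 was at -2.05 ± 0.44. The fructokinase gene sacK1, high on GMOS, was at -2.01 ± 0.44 on mannose. The genes pts35A and pts35C belong to the list of other PTS genes, while the rest here belong to no list that was tested. None of these genes passed without either glucose array or without either mannose array.

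The galactose arrays stood apart, and galactose replicate 2 lay nearer to the GMOS arrays. If that array held RNA of a GMOS culture alone, the 12 galactose genes fixed beforehand would lie near the GMOS arrays, but their median lay 3.10 above GMOS, with 9 of the 12 over 1 log2 unit above. Of 21 genes higher on GMOS, chosen without the galactose arrays, 12 lay over 1 log2 unit below the GMOS mean in that array, and their median was -1.55. A mix of RNA from both cultures was not tested. It would raise the genes of the PTS and sucrose clusters in galactose replicate 2. Over both galactose arrays pts23B, pts23C and pbg6 stood at 0.10 ± 0.49, -0.59 ± 0.73 and -0.33 ± 0.59 against glucose. The sucrose cluster ran from -1.36 (sacK1) to -0.90 (scrB), but pts23A stood at 1.70 ± 0.57. Apart from pts23A, these values argue against a large share of GMOS RNA, while a small share stays open. If noise from the low signal of galactose replicate 1 were the source, dim genes would differ most. Instead, 36.0% of the 780 brightest genes differed over 2-fold between the duplicates, against 7.44% of the 780 dimmest, and 20.4% of the brightest in the GMOS pair. That speaks against noise in dim genes only. The 75th percentiles were 291 and 565 while the highest signals were 283423 and 307821, so the percentile shift could itself set bright genes apart. An effect of the low signal through the scaling thus stays open. A difference in state between the duplicate cultures stays open too, and no biological explanation was tested.

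The 11 called members of the amino acid list, 10 synthesis genes and the tRNA synthetase gene asnS1, were lower on GMOS than on glucose, with a median of -2.64. A slide row effect would lower them on mannose too, which shares the row of GMOS, but their median for mannose against glucose was -0.18. Members went both ways around that median. The log2 signal of aroI was -0.15 and -1.02 on glucose and -1.41 and -2.27 on mannose. That of asnA was 4.20 and 4.30 on glucose and 4.87 and 5.05 on mannose. For members such as aroI, a row effect on part of the fall stays open. Each scan held 1 array of each of these sugars, and the median was -2.88 in the first scan and -2.56 in the second, values that decide little since a call from these same pairs needs both to be low. The state of the culture other than its sugar stays open: between the duplicate galactose cultures the same 11 genes differed by a median of 1.32, against 0.55 for all genes, with all 11 higher in replicate 1. Between the glucose, GMOS and mannose duplicates they differed by 0.56, 0.45 and 0.56, against 0.23, 0.48 and 0.51 for all genes. These genes may thus follow both the sugar and the state of the culture, which this design does not separate.

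Of the 9 genes in the PTS and sucrose clusters, all but pts23A were called higher on GMOS than on each monosaccharide. Cross-hybridisation with a transcript outside the clusters would need one that rises as much. Against galactose the lowest rise of pts23B, pts23C and pbg6 was 3.82 ± 0.86 above the largest outside, orf40 (2.76), and that of sacK1, pts1BCA and lp_0189 was 1.77 ± 0.85 above it. For scrR and scrB the margin was 0.79 ± 0.87, within its error. These margins decide little, since the 8 genes were chosen by their calls, which include this comparison, where no other gene was called higher. They were also grouped after their values were seen. Of the 24 probes of the 8 genes, 0 were marked as cross-hybridising, but cross-hybridisation stays open for all 8. A slide row effect would raise the genes on mannose too, but among the 8 genes higher on GMOS than on glucose and galactose, a choice made without mannose, the highest value for mannose against glucose was -1.20, while the smallest for GMOS was 2.64. A response to GMOS is a hypothesis that stays open beside one to other sugars in the preparation, such as sucrose, which were not tested.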
